A study of Mus musculus with 9 samples.

How the data were processed

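Each of the 9 libraries is 1 clone in 1 condition, and the series describes the 3 clones as biological replicates, all derived from the AML246 line. Per the labels' protocols, cells were sorted by GFP, lysed, and RNA was prepared on the same day with a QIAGEN RNeasy plus kit before Illumina library preparation. Per the submitters' processing notes, CASAVA 1.8.2, featureCounts, edgeR 3.8.2, limma 3.22.0 and the mm10 build were used; the aligner, the annotation version, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited values are raw read counts per Entrez gene, per the file headers, with 1 file for each library and no normalization. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart, and reads of paralogs and pseudogenes may be shared.

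Gene symbols and coordinates came from the RefSeq table of the assembly GRCm38, the build also called mm10. Of the 27179 entries, 25275 matched a symbol and 1904 did not; the latter stayed in the tests but were not named. Library totals ran from 7408118 to 9803258 counts. In untreated clone 1, 22.0% of counts lay on the entry 100861531, against 0.153% to 1.64% in the other libraries. This entry has no symbol in the RefSeq table used, and what it encodes was not examined. The TMM factor of untreated clone 1 was 0.736, against 0.916 to 1.18 in the others. Libraries were compared in pairs for duplicates: the closest pair, untreated and washed clone 4, had a chi-square of 3.62 per degree of freedom, beyond sampling noise, so each library counted once.

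Genes were filtered with filterByExpr, which left 12004, and scaled by TMM. edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with a mean for each of the 3 groups to all 9 libraries, and 3 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. CPM values are scaled by TMM, and log2 CPM used a prior count of 2. SE is the log2 fold change divided by the square root of its F statistic. Clone differences were tested in a model with group and clone, and the response of clones in a model with clone, hairpin state and their interaction. P-values measure the spread between clones of 1 line, not between leukaemias. Doxycycline, the GFP gate and the hairpin change together in this design.

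The clone number was checked as a pairing. Deviations from the group means correlated between libraries of the same clone at 0.29 to 0.68 in all 9 pairs of groups and clones. With groups ordered untreated, doxycycline and washed, each exceeded the correlations of the pair's first library with other clones. Seen from the second library this was not examined. Doxycycline clone 2 reached 0.32 with a washed library of another clone, against 0.29 between the clone 4 libraries. Deviations cancel out within a group, which lowers correlations with other clones. The same clone is the same cell line, so the numbers pair the libraries. The fit with clone as a block was an alternative. Its list tests stand beside lists whose call it changed, and its counts of called list members beside counts that it moved by more than 1.5-fold in either direction.

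Before the data were examined, 29 lists of genes were fixed from general knowledge of blood cells, 725 names of which 708 matched, covering neutrophil granules (primary, secondary and tertiary), mature neutrophils, monocytes, dendritic cells, PU.1 targets, NADPH oxidase, transcription factors, progenitors, other blood lineages, and cell cycle, ribosome, metabolic, stress and death genes. Lists were tested with camera from limma 3.58.1 with an inter-gene correlation of 0.01, with that correlation estimated, and with fry, adjusted over 29 lists and 3 contrasts. The rule for named genes, fixed at the same time, took Spi1 and Trp53, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 3 and 1 direction in all clones, up to 4 genes of smallest p per list, and for the clone tests the 10 of smallest p. Results for a few genes are not reported here.

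The pipeline was tested on simulated counts with 200 of 12004 genes changed. The simulated spread was that of the fit with clone as a block, and only 200 other genes differed between clones. The recovery therefore leaves out spread between clones that the fit without the block carries. For doxycycline against untreated, edgeR recovered 38% of the 2-fold and 92% of the 4-fold changes with 1 false call; for washed against doxycycline 36% and 93% with 3. Alternatives were RLE size factors, library size alone, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, glmTreat against a fold of 1.5, the 2 groups alone, and leaving out each clone. Added after the data were seen were the fits without the washed or the untreated library of clone 1, with the block and without the washed one, and without mitochondrial genes and entries lacking a symbol, and the block for the hypoxia list. Figures were drawn with matplotlib from the result tables.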

Results

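RNA was sequenced from AML246 cells, a mouse acute myeloid leukaemia line on a C57BL/6 background that lacks p53 and carries a short hairpin RNA against PU.1, the myeloid transcription factor encoded by Spi1. The cells were grown with the cytokine IL3, and clones 1, 2 and 4 had each been started from a single cell. Each of the 3 clones was measured in 3 conditions, which gave 9 libraries with 3 per group. Untreated cells and washed cells were sorted as GFP-high, the state in which the hairpin is made. Cells kept for 14 days in doxycycline were sorted as GFP-off, the state in which the hairpin is switched off. Washed cells had 14 days of doxycycline followed by 14 days without it. The files held whole-number counts for 27179 gene entries, and the library totals ran from 7408118 counts for untreated clone 1 to 9803258 for doxycycline clone 1. A total of 12004 genes passed the filter on low counts and were tested.

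Spi1 (Entrez gene 20375, chromosome 2, 91082374 to 91115759 on GRCm38) was reported first, because the hairpin is directed against it. It stood at 48.1, 46.6 and 23.7 CPM in untreated clones 1, 2 and 4. In doxycycline it stood at 197, 191 and 156 CPM, a ratio of 4.11, 4.10 and 6.57 within the clones. After washout it stood at 52.0, 40.6 and 23.9 CPM. Spi1 rose in doxycycline (log2 fold change 2.20 ± 0.34 SE, adjusted p = 0.00623) and fell after washout (log2 fold change -2.22, adjusted p = 0.00597). The washed and untreated groups differed by less than the spread between clones (log2 fold change -0.02 ± 0.33 SE, adjusted p = 1). In each clone the doxycycline library had the highest level. For doxycycline against untreated the call stood without clone 1 (log2 fold change 2.30, adjusted p = 0.0200) and was lost without clone 2 (2.30, adjusted p = 0.0816) and without clone 4 (2.03, adjusted p = 0.103). For washed against doxycycline it likewise stood without clone 1 (-2.43, adjusted p = 0.0162) and was lost without clone 2 (-2.21, adjusted p = 0.0975) and without clone 4 (-2.05, adjusted p = 0.0997).

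**Figure D1:**
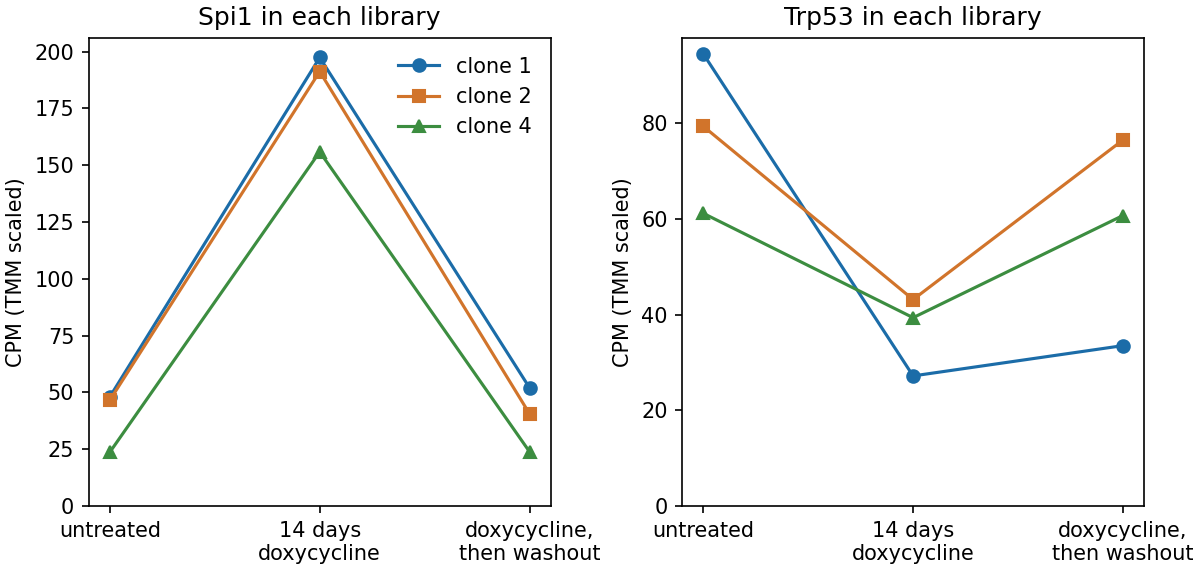
Level of Spi1 and Trp53 in CPM in each of the 9 libraries, with 1 line per clone across the 3 conditions. Spi1 lies at 156 to 197 CPM in the doxycycline libraries and at 23.7 to 52.0 CPM in the others, and Trp53 in washed clone 1 lies at 33.5 CPM, below the other washed libraries.

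Transcripts assigned to Trp53 (Entrez gene 22059, chromosome 11, 69580348 to 69591873 on GRCm38), the gene for p53, were counted in every library although the labels describe the cells as p53-deficient. Counts per gene cannot show which exons they came from. The level was 78.3 ± 16.7 CPM in untreated cells and 36.6 ± 8.34 CPM in doxycycline (SD, n = 3 per group), which missed the threshold (log2 fold change -1.10, adjusted p = 0.0559) and passed it with the clone as a block (adjusted p = 0.0226).

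The first comparison asked which genes change when the PU.1 hairpin is switched off by doxycycline. Of the 18 tested genes of the mature neutrophil list 15 rose and 0 fell. S100a9, a subunit of the calprotectin complex of neutrophil cytosol, went from 8.56 ± 5.91 to 635 ± 337 CPM (SD, n = 3 per group, adjusted p = 0.0018). Lcn2, the siderophore-binding granule protein lipocalin 2, went from 4.97 ± 1.58 to 172 ± 84.5 CPM (adjusted p = 0.000865). Ncf1, the p47phox subunit of the NADPH oxidase, had the smallest p of its list and went from 51.9 ± 8.01 to 599 ± 61.4 CPM (adjusted p = 0.000188). Il9r, the interleukin 9 receptor chain, fell from 156 ± 46.8 to 0.617 ± 0.268 CPM (adjusted p = 0.00256).

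In all, 1311 of the 12004 genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 789 higher and 522 lower, and each of the 1311 moved the same way in all 3 clones. Of these, 535 rose and 386 fell by at least 2-fold. With the clone as a block, 2976 genes passed, 1566 higher and 1410 lower, and all 1311 were among them. With scaling by library size alone the call count was 1053, of which 75.6% were higher, against 60.2% with TMM scaling; that scaling moved the median log2 fold change of all genes from 0.00 to 0.23. The unblocked call count rested on the clones present: it was 967 without clone 1, 159 without clone 2 and 0 without clone 4. Blocked fits called 2106 of the 12004 genes higher and 1946 lower without clone 1. They called 382 and 239 without clone 2, and 219 and 141 without clone 4. The unblocked count was 347 without the untreated library of clone 1 alone and 2258 without the washed library of clone 1 alone.

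Among the further genes with the largest rises were Rflnb, from 5.88 to 230 CPM, Gapt, a membrane adaptor of blood cells, from 7.14 to 211 CPM, and Cyp2a5, from 33.6 to 757 CPM. Alox15, the arachidonate 15-lipoxygenase, went from 17.1 to 584 CPM, and Antxr2, an anthrax toxin receptor, from 2.53 to 60.9 CPM. The stefin-like genes Cstdc4 and Cstdc5 also rose, to 92.1 and 395 CPM, but they belong to a family of near-identical genes whose reads the counting could split between copies. Among the largest falls were Tph1, an enzyme of serotonin synthesis, from 47.7 to 0.209 CPM, Matn1 from 86.2 to 1.48 CPM and Muc13, a cell surface mucin, from 49.5 to 1.46 CPM. Gstm5, a glutathione transferase, fell from 510 to 32.0 CPM, Ptpru, a receptor tyrosine phosphatase, from 84.6 to 4.00 CPM, and Unc5a, Enpp1, Ppm1l and Dmwd each fell from 33.9 to 52.5 CPM to at most 3.32 CPM.

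Adjusted over the mature neutrophil list alone, 15 of its members rose and 1 fell. Clec4e, a receptor for fungal and mycobacterial lipids, rose from 2.62 to 32.1 CPM, Pglyrp1, a bactericidal granule protein, from 130 to 776 CPM, and Ccl6, a chemokine, from 0.556 to 40.9 CPM. Of the 19 tested secondary and tertiary granule genes, 11 rose and 0 fell (13 and 1 adjusted over the list alone, 12 and 1 with the clone as a block), among them Padi4, the histone citrullinating enzyme, from 78.0 ± 10.9 to 245 ± 32.4 CPM. The 15 tested genes of the NADPH oxidase and phagocytosis list gave 11 higher and 0 lower (12 and 1 adjusted over the list alone), with Coro1a, an actin regulator, from 139 to 798 CPM. The 23 tested PU.1 target and myeloid receptor genes gave 13 higher and 0 lower (15 and 2 adjusted over the list alone), with Itgam, the integrin CD11b, from 59.6 to 745 CPM and Sirpa, an inhibitory receptor, up to 430 CPM. The 19 tested chemotaxis and adhesion genes gave 10 higher and 1 lower, with the same numbers adjusted over the list alone; Cxcr2, the chemokine receptor of neutrophils, rose from 2.68 to 22.2 CPM and Cx3cr1, the fractalkine receptor of monocytes, fell from 13.7 to 0.367 CPM. These lists share members: 16 of the 26 PU.1 target genes and 9 of the 27 mature neutrophil genes are also in another list. All 5 lists passed camera with the preset correlation of 0.01, with adjusted p from 7.95e-19 for mature neutrophil to 1.35e-07 for chemotaxis and adhesion. With an estimated correlation, mature neutrophil (adjusted p = 0.00677) and NADPH oxidase (adjusted p = 0.0442) passed, and PU.1 target (adjusted p = 0.0548), chemotaxis (adjusted p = 0.0548) and secondary granule genes (adjusted p = 0.0687) did not. By fry all 5 passed, with adjusted p from 6.59e-05 for mature neutrophil to 0.00362 for secondary granule genes.

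**Figure D2:**
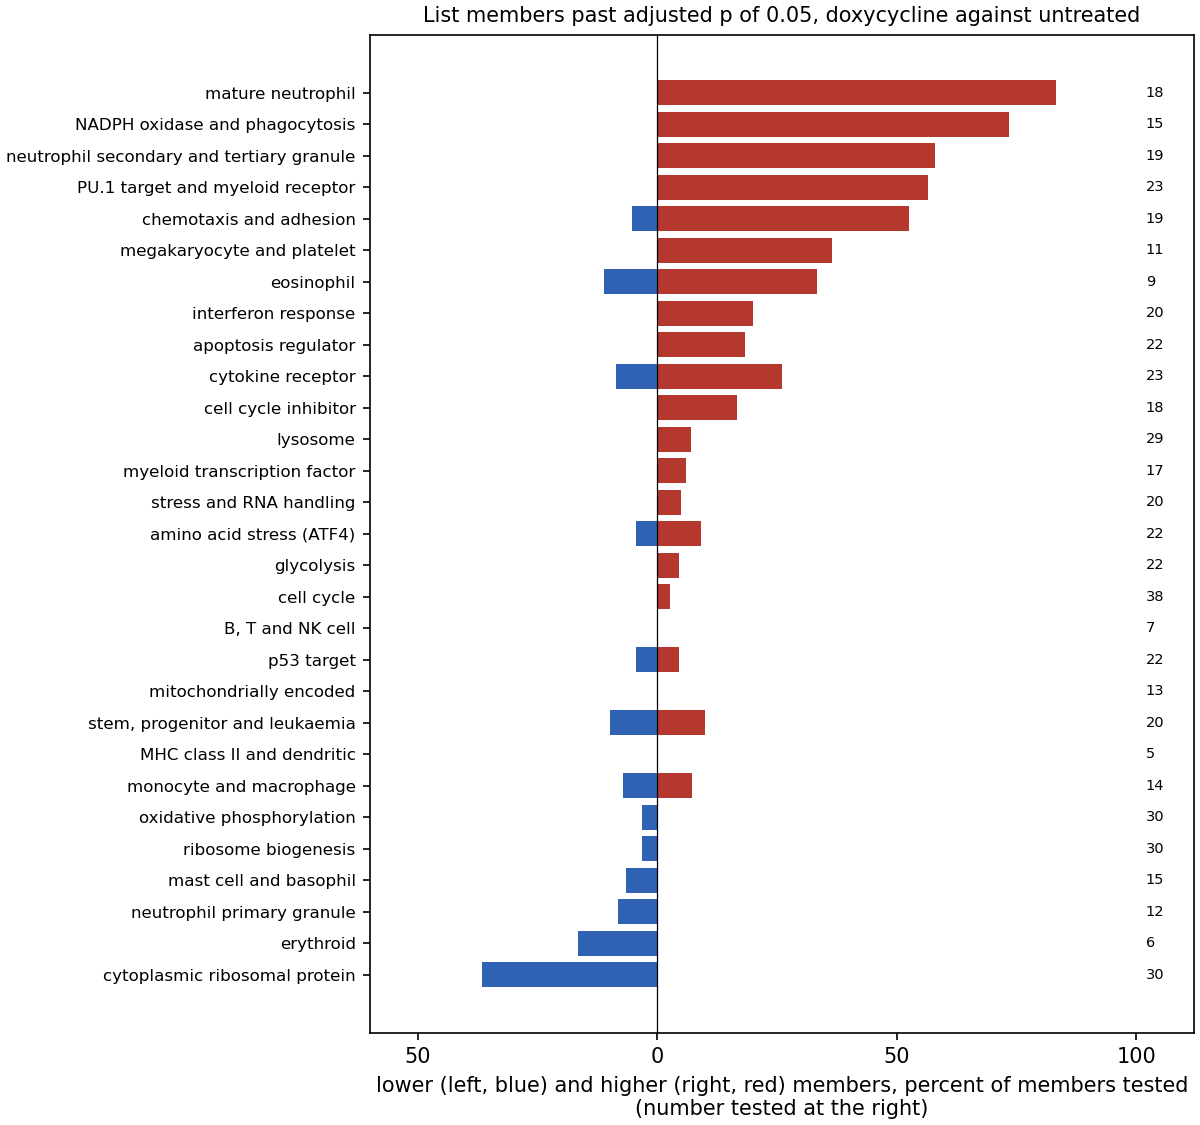
Share of the tested members of each of the 29 gene lists that passed an adjusted p of 0.05 in doxycycline against untreated, in percent, with higher members to the right, lower members to the left and the number tested at the edge. The mature neutrophil list leads with 15 of 18 higher, and cytoplasmic ribosomal protein genes close the plot with 11 of 30 lower.

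Of the 12 tested members of the primary granule list, which holds genes of granules made earlier in neutrophil development and also others such as Igfbp4 and Hmgn2, 0 were higher and 1 was lower, with the same numbers adjusted over the list alone, and 1 and 4 with the clone as a block. The lower one without the block was Igfbp4, a secreted insulin-like growth factor binding protein and not a granule protein, from 224 ± 99.7 to 18.3 ± 3.26 CPM. The list did not pass camera (adjusted p = 0.153) but passed downwards with the clone as a block (adjusted p = 0.0318, and 0.636 with the block and an estimated correlation), and its median turned from -0.24 to 0.08 with scaling by library size alone. Of the 14 tested monocyte and macrophage genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone, 2 and 4 with the block): Fcgr1, the high-affinity IgG receptor, stood at 0.126 and 7.46 CPM, and Cx3cr1 fell. The monocyte list did not pass camera (adjusted p = 0.327). Of 5 tested MHC class II and dendritic genes (camera adjusted p = 0.907, downwards, with a median of 0.20 and a mean of 0.07) and 7 tested B, T and NK cell genes (camera adjusted p = 0.683) 0 passed edgeR's test, also adjusted over the list alone; with the block 0 and 0 were higher, and 1 and 2 lower.

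Of the 11 tested megakaryocyte and platelet genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone): Itga2b, the integrin CD41, from 169 to 541 CPM, Itgb3, its partner chain, from 35.5 to 133 CPM, the matrix protein Thbs1 from 965 to 3549 CPM and the thrombin receptor subunit F2rl2 from 6.94 to 68.0 CPM. This list passed camera (adjusted p = 0.000292) and not with an estimated correlation (adjusted p = 0.122). Of the 9 tested eosinophil genes, 3 rose and 1 fell, with the same numbers adjusted over the list alone (3 and 2 with the block). Siglecf, a sialic acid receptor, rose from 0.719 to 27.5 CPM, and Il5ra, the interleukin 5 receptor, from 0.739 to 7.27 CPM, along with Alox15, while the eosinophil peroxidase gene Epx fell from 8743 ± 1892 to 3443 ± 1167 CPM. The eosinophil list did not pass camera (adjusted p = 0.597), with a median of -0.52 and a mean of 0.99. Of the 15 tested mast cell and basophil genes, 0 rose and 1 fell, with the same numbers adjusted over the list alone (0 and 5 with the block): Cma1, a mast cell chymase, went from 5.84 to 0.347 CPM. This list missed the threshold (adjusted p = 0.0505) and passed downwards with the block (adjusted p = 0.0138), and not with the block and an estimated correlation (adjusted p = 0.563). Of the 6 tested erythroid genes 0 rose and 1 fell, the erythropoietin receptor Epor, down to 1.42 CPM, with the same numbers adjusted over the list alone; the list passed camera downwards (adjusted p = 0.0469) and not with an estimated correlation (adjusted p = 0.578).

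Stem, progenitor and leukaemia genes went both ways. Of 20 tested, Kit, the stem cell factor receptor, rose from 74.0 ± 17.9 to 215 ± 69.0 CPM and Cd34, a surface marker of progenitors, from 19.9 to 182 CPM, while Muc13 and the adhesion receptor Adgrg1 fell, the latter from 933 ± 88.5 to 276 ± 40.2 CPM; the 4 were the same adjusted over the list alone, and with the block 2 rose and 5 fell. The list did not pass camera (adjusted p = 0.479), and its median of 0.06 and mean of -0.28 differed in sign. Of 23 tested cytokine receptor genes, 6 rose and 2 fell (8 and 2 adjusted over the list alone), with Tgfbr2, a transforming growth factor receptor, from 32.9 to 134 CPM, Csf2ra, the GM-CSF receptor chain, from 17.3 to 43.1 CPM and Ifngr1, an interferon gamma receptor chain, down from 523 to 255 CPM. The list missed camera's threshold without the block (adjusted p = 0.0637) and passed with it (adjusted p = 0.043). Without the block it passed fry (adjusted p = 0.0344). It did not pass with an estimated correlation (adjusted p = 0.476, and 0.438 with the block). Of 17 tested myeloid transcription factor genes, 1 rose, Stat3, from 98.2 to 229 CPM, with the same number adjusted over the list alone and 2 with the block (camera adjusted p = 0.431). Cebpe, a transcription factor of late granulocyte development, stood at 257 ± 61.1 and 455 ± 78.1 CPM (adjusted p = 0.127, 0.0113 with the block).

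Of 30 tested cytoplasmic ribosomal protein genes, 0 rose and 11 fell (0 and 23 adjusted over the list alone, 0 and 22 with the block), with Rpl3 from 254 to 113 CPM and Rps24 from 291 ± 32.6 to 135 ± 7.66 CPM. Their many processed pseudogenes make each single value uncertain. The list passed camera (adjusted p = 4.77e-10) and not with an estimated correlation (adjusted p = 0.516). Of 30 tested ribosome biogenesis genes 0 rose and 1 fell, Npm1, the nucleolar chaperone nucleophosmin, from 416 to 181 CPM, with the same numbers adjusted over the list alone (0 and 6 with the block); the list passed downwards (adjusted p = 0.0295) and not with an estimated correlation (adjusted p = 0.767).

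Of 20 tested interferon response genes 4 rose and 0 fell (6 and 0 adjusted over the list alone, 9 and 0 with the block), with Parp14 from 4.52 to 18.5 CPM. The list passed camera (adjusted p = 0.00319) and not with an estimated correlation (adjusted p = 0.516). Of 38 tested cell cycle genes 1 rose, E2f1, from 17.0 to 33.3 CPM, and none did adjusted over the list alone (5 rose and 0 fell with the block); the list passed upwards (adjusted p = 0.0295), not with an estimated correlation (adjusted p = 0.767), and its median within clones was 0.64, -0.19 and 0.49 for clones 1, 2 and 4. Of 18 tested cell cycle inhibitor genes 3 rose and 0 fell (5 and 0 adjusted over the list alone, 6 and 1 with the block), with Mxd1, a MYC antagonist, from 39.7 to 148 CPM. The list missed camera's threshold without the block (adjusted p = 0.0591) and passed with it (adjusted p = 0.037), and not with the block and an estimated correlation (adjusted p = 0.636). Of 22 tested genes of the ATF4 amino acid stress list 2 rose and 1 fell, with the same numbers adjusted over the list alone (2 and 8 with the block): the stress-response factor Atf3 and the cystine transporter Slc7a11 rose to 17.1 and 43.1 CPM, and the pseudokinase Trib3 fell from 41.9 to 6.72 CPM. That list passed downwards (adjusted p = 0.019) and not with an estimated correlation (adjusted p = 0.516).

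Apoptosis regulators gave 4 higher and 0 lower of 22, with the same numbers adjusted over the list alone (7 and 1 with the block), among them the caspase inhibitor Xiap, from 35.9 to 93.7 CPM, and Bak1, a pore-forming death protein, from 50.4 to 91.2 CPM (camera adjusted p = 0.0686). p53 target genes gave 1 higher, Pmaip1, and 1 lower, Phlda3, of 22, with the same numbers adjusted over the list alone and 3 and 2 with the block (camera adjusted p = 0.579). Lysosomal genes gave 2 higher and 0 lower of 29 (6 and 0 adjusted over the list alone, 9 and 0 with the block), with the ceramidase Asah1 from 97.8 to 249 CPM (camera adjusted p = 0.0617). Of 20 stress and RNA handling genes 1 rose, Atf3, also adjusted over the list alone, and 2 with the block (camera adjusted p = 0.891; median -0.21, mean 0.08).

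Of 22 tested glycolysis genes 1 rose and 0 fell, with the same numbers adjusted over the list alone, while with the block 1 rose and 8 fell: Hk3, a hexokinase of myeloid cells, went from 18.2 to 76.8 CPM. Ldha, lactate dehydrogenase A, stood at 2376 ± 788 CPM untreated and 897 ± 506 CPM in doxycycline (adjusted p = 0.145, 0.0181 with the block). The glycolysis list missed camera's threshold without the block (adjusted p = 0.118) and passed downwards with it (adjusted p = 0.0254). It did not pass with the block and an estimated correlation (adjusted p = 0.690), and its mean level differed widely between libraries of one group. Of 30 tested oxidative phosphorylation genes 1 fell, Ndufb5, a complex I subunit, and none did adjusted over the list alone, while with the block 1 rose and 3 fell (camera adjusted p = 0.143; the median of -0.16 became 0.07 with scaling by library size alone). None of the 13 mitochondrially encoded genes passed, also adjusted over the list alone. Their list missed camera's threshold without the block (adjusted p = 0.0904) and passed downwards with it (adjusted p = 0.0499), and not with the block and an estimated correlation (adjusted p = 0.714). The share of counts on the mitochondrial genome was 12.7%, 16.8% and 20.4% in untreated clones 1, 2 and 4, and 2.66%, 18.6% and 7.52% in doxycycline.

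The second comparison asked what changes when the hairpin is made again after washout. Of the 789 genes that had risen in doxycycline, 627 were called lower after washout. S100a9 went from 635 ± 337 to 9.36 ± 4.24 CPM, Itgam from 745 ± 113 to 30.3 ± 3.96 CPM and Ncf1 had a log2 fold change of -3.60 ± 0.20 SE (adjusted p = 0.000161). Tph1 rose from 0.209 to 50.7 ± 34.1 CPM, Il9r from 0.617 to 132 ± 107 CPM and Gstm5 from 32.0 to 426 ± 181 CPM (SD, n = 3 per group). Cttn, the actin-binding protein cortactin, rose from 6.81 to 74.8 ± 4.19 CPM, and Lipg, endothelial lipase, fell from 220 to 9.34 CPM.

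A total of 1160 genes passed the edgeR test, 437 higher and 723 lower, and 1158 of them moved the same way in all 3 clones. With the clone as a block 2744 passed, 1252 higher and 1492 lower. In the next counts the numbers in parentheses are those higher and lower adjusted over the list alone. Of the mature neutrophil list 14 of 18 fell (1 and 15), of the NADPH oxidase list 11 of 15 (0 and 11), of the PU.1 target list 13 of 23 (0 and 15), of the secondary and tertiary granule list 9 of 19 (0 and 12) and of the chemotaxis list 9 of 19, with Cx3cr1 alone higher (1 and 12). Of the megakaryocyte and platelet list 5 of 11 fell (0 and 5), of the interferon response list 5 of 20 (0 and 8; with the block 0 and 13) and of the cytokine receptor list 6 of 23, with 2 higher (2 and 8). Cytoplasmic ribosomal protein genes gave 4 of 30 higher (14 and 0, the same with the block), among them Rps2 and Rps4x. By camera, 17 of the 29 lists passed, 6 higher and 11 lower. With an estimated correlation mature neutrophil (adjusted p = 0.0075) and NADPH oxidase (adjusted p = 0.0442) passed; the adjusted p was 0.0548 for PU.1 target, 0.0548 for chemotaxis, 0.0698 for secondary granule, 0.0687 for megakaryocyte, 0.318 for interferon, 0.241 for cytokine receptor and 0.578 for ribosomal protein genes.

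Among the remaining lists that passed camera, primary granule, ribosome biogenesis, oxidative phosphorylation, ATF4 and erythroid genes passed upwards. Igfbp4, which is not a granule protein, was the 1 called member of 12 in the primary granule list (4 higher adjusted over the list alone), Npm1 the 1 of 30 ribosome biogenesis genes and Epor the 1 of 6 erythroid genes (1 each adjusted over the list alone). With the block 5 members of the primary granule list, 9 of the ribosome biogenesis list and 2 of the erythroid list were higher and 0 lower. Ndufb5 and Ndufa10 were the 2 of 30 oxidative phosphorylation genes (0 adjusted over the list alone). The 1 called member of 22 in the ATF4 list, Atf3, fell (2 higher and 1 lower adjusted over the list alone, 7 and 2 with the block). Cell cycle inhibitors (4 of 18 lower, with Mxd1 and Btg2, and 4 adjusted over the list alone), apoptosis regulators (2 of 22 lower, Xiap and Pmaip1, and 2 adjusted over the list alone) and lysosomal genes (4 of 29 lower, with Asah1 and Npc1, and 7 adjusted over the list alone) passed downwards. With the block 7, 8 and 8 of these genes were lower and 0 higher. With an estimated correlation none of these 8 passed, with adjusted p from 0.516 for the ATF4 list to 0.702 for oxidative phosphorylation. Mast cell genes missed camera's threshold without the block (adjusted p = 0.0686) and passed upwards with it (adjusted p = 0.0236), and not with the block and an estimated correlation (adjusted p = 0.565). Of the 17 lists, 9 passed in the same direction without the washed library of clone 1. Median and mean differed in sign in the eosinophil list (0.41 and -0.77) and the stress and RNA handling list (0.04 and -0.10), neither of which passed. The call count of 1160 was 70 without clone 2, 4 without clone 4, 717 without the untreated library of clone 1 and 1814 without the washed library of clone 1. It was 648 with scaling by library size alone, and 324 when only the 6 libraries compared were fitted.

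Of the 1311 genes called in doxycycline against untreated, 987 (75.3%) were also called in the opposite direction after washout, 627 higher and then lower and 360 lower and then higher, and 0 were called in the same direction in both. S100a9, Lcn2, Ncf1, Itgam, Alox15 and Kit were among the former, and Tph1, Il9r, Muc13, Gstm5, Epx and Npm1 among the latter. Olfm4, a granule protein, stood at 377 CPM untreated, 3483 CPM in doxycycline and 621 CPM after washout, and the washed level missed the threshold against doxycycline (adjusted p = 0.07, 0.0035 with the block). Independent lists of the same sizes would share 47.5 and 19.0 genes. The 2 comparisons share the doxycycline libraries. In 20 simulations of unchanged groups at most 0 genes were reversed, but unchanged groups give hardly any calls that could reverse. That count therefore does not show how much the sharing adds once genes are called. Across genes, which are not independent replicates, the fold changes of the 2 comparisons had a correlation of -0.945, against -0.496 in the simulations, and a covariance of -0.923 against -0.0936. The 3 shared libraries are too few to split, so part of the excess may come from them. The blocked fit of all libraries gave 2271 reversed genes. Unblocked, the fit without clone 2 gave 68 and the fit without clone 4 gave 0. Without the untreated library of clone 1 the number was 343, without the washed library of clone 1 it was 1660, and with scaling by library size alone it was 594.

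The third comparison asked whether cells that had passed through doxycycline differed from cells that never had it. No gene was called by edgeR, with or without the clone as a block, and 38 genes lay at an unadjusted p under 0.05 (98 with the block). DESeq2 and limma voom also called 0 genes. Genes that had risen in doxycycline lay at a median log2 difference of 0.08 between washed and untreated cells, and those that had fallen at -0.09; the untreated libraries of this difference also served to choose the genes. With genes called by a blocked fit of the other clones, the medians of risen and fallen genes were 0.10 and -0.30 in clone 1, -0.04 and 0.06 in clone 2 and -0.01 and -0.02 in clone 4. Without the block they were 0.18 and -0.55 in clone 1 and -0.01 and 0.08 in clone 2, and no genes were called for clone 4. Epx stood at 8743 ± 1892 CPM untreated and 8590 CPM washed, Adgrg1 at 933 and 831 CPM and Spi1 at 39.5 ± 13.7 and 38.8 ± 14.2 CPM. On simulated counts with no change in this comparison edgeR made 0 calls among the 12004 genes.

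The clones differed in how closely the washed library matched the untreated one. The correlation across genes was 0.988 in clone 2 and 0.991 in clone 4, and 0.922 in clone 1. Between the washed and the doxycycline library it was 0.903 in clone 2, 0.915 in clone 4 and 0.923 in clone 1. The share of counts on the mitochondrial genome was 3.28% in washed clone 1 and 15.8% and 22.0% in washed clones 2 and 4, and the mean level of the stress and RNA handling list, as log2 CPM minus the mean of each gene over all libraries, was -1.18, 0.32 and 0.26. In washed clone 1, Mpo, the gene of the primary granule enzyme myeloperoxidase, stood at 1720 CPM, against at most 82.7 CPM in the other washed and the untreated libraries. Ctsg, cathepsin G of the same granules, stood at 952 CPM against 110 to 274 CPM, and Hmga2, a chromatin protein, at 106 CPM against 6.86 to 38.3 CPM. Csf1r, the receptor of macrophage colony-stimulating factor, stood at 0.552 CPM against at least 13.8 CPM. Hmga2 and Csf1r were chosen after their values were seen.

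By camera 13 lists passed between washed and untreated cells. The primary granule list, cell cycle genes, ribosome biogenesis genes and oxidative phosphorylation genes were higher. PU.1 target, cell cycle inhibitor, cytoplasmic ribosomal protein, mitochondrially encoded, glycolysis, interferon response, chemotaxis, lysosomal and megakaryocyte genes were lower. None passed with an estimated correlation (adjusted p from 0.495 to 0.671), and 0 of their members were called, also adjusted over the list alone. With scaling by library size alone the medians of the ribosomal protein (-0.15 to 0.03), lysosomal (-0.10 to 0.05) and megakaryocyte lists (-0.12 to 0.10) changed sign, as the median of all genes moved from 0.02 to 0.22. Myeloid transcription factor genes and stress and RNA handling genes missed camera's threshold without the block (adjusted p = 0.0591 and 0.0755). With it they passed downwards (adjusted p = 0.0106 and 0.0123), and not with the block and an estimated correlation (adjusted p = 0.526 and 0.563). Unblocked, the former also passed downwards without mitochondrial and unnamed entries (adjusted p = 0.0448). The latter did so without the untreated library of clone 1 (adjusted p = 0.0297). Leaving out clone 1 altogether kept 0 of the 13 calls, and 5 lists passed, 4 of them opposite to their direction with all libraries. Without the washed library of clone 1 alone, 0 of the 13 calls held in their direction. The primary granule list (adjusted p = 0.0454) and the cell cycle list (adjusted p = 0.000969) passed in the opposite one, and the mast cell list, not among the 13, passed upwards (adjusted p = 0.00946; 0.661 and downwards with all libraries). With the block and without that library these 3 lists did not pass (adjusted p = 0.446, 0.963 and 0.950). In that fit 2 of the 13 calls remained, oxidative phosphorylation upwards (adjusted p = 0.0179) and glycolysis downwards (adjusted p = 0.0204). The secondary and tertiary granule list passed upwards (adjusted p = 0.0268). That fit still draws on the untreated and doxycycline libraries of clone 1, so its calls are not free of clone 1. From untreated to washed, the mean level of the glycolysis list went from 0.83 to 0.90 in clone 2 and from -0.30 to -0.29 in clone 4, against the call. That of the oxidative phosphorylation list went from 0.04 to 0.14 in clone 2 and from -0.04 to -0.08 in clone 4. Without the untreated library of clone 1, 10 of the 13 held, and the secondary and tertiary granule list, not among the 13, passed upwards (adjusted p = 0.0161; 0.683 and downwards with all libraries). Within clones, the median log2 difference of the primary granule list was 1.10 in clone 1, -0.14 in clone 2 and -0.11 in clone 4, and that of the glycolysis genes was -1.51, 0.11 and -0.02.

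**Figure D3:**
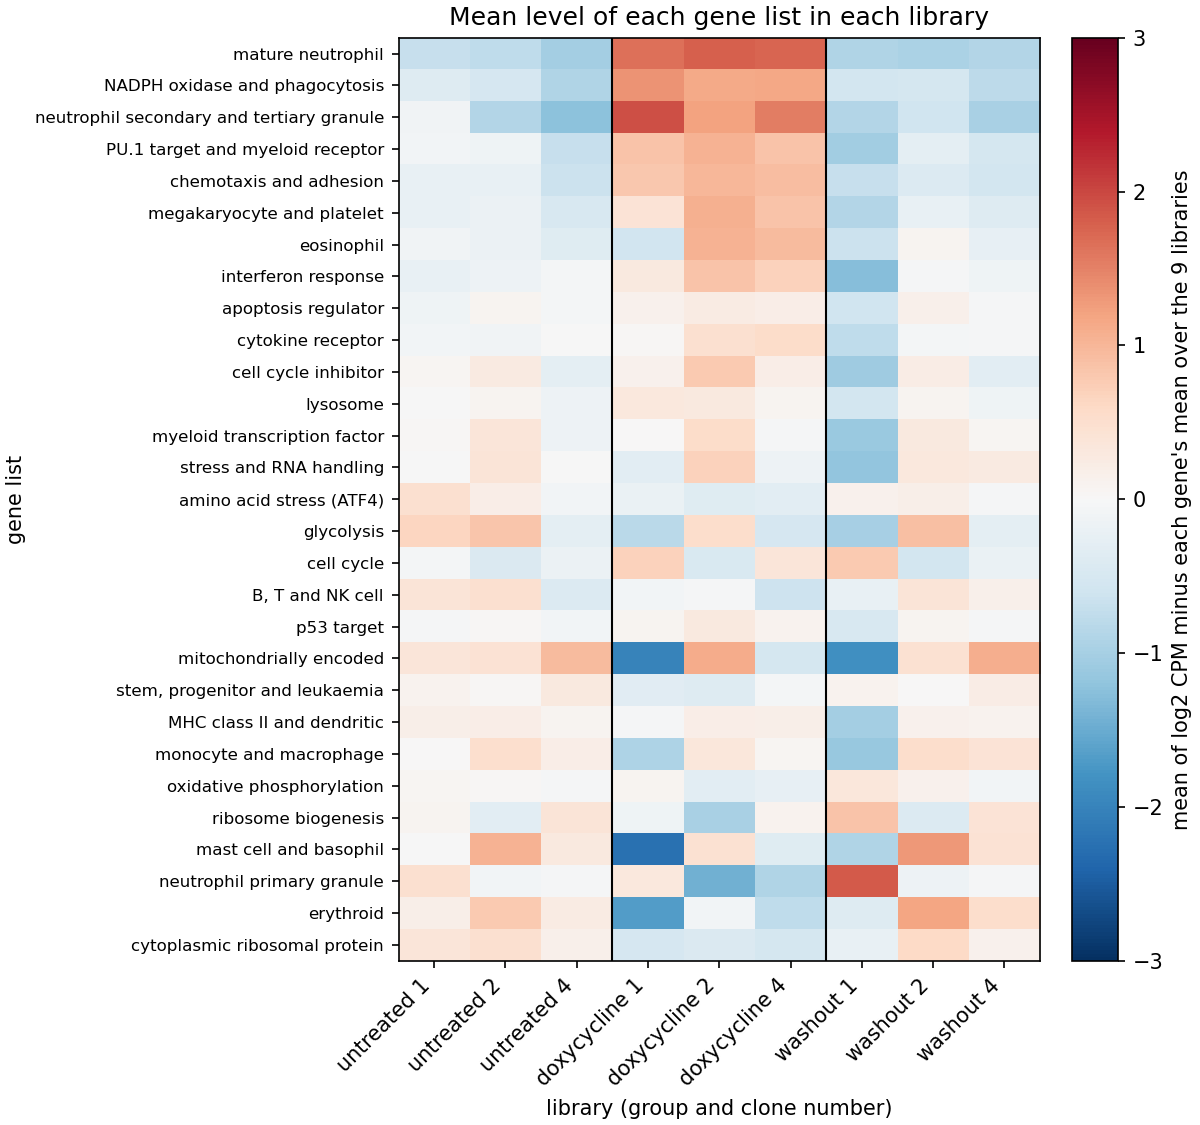
Mean level of each of the 29 gene lists in each of the 9 libraries, as log2 CPM minus the mean of each gene over all libraries, with red above and blue below that mean. The mature neutrophil list and the secondary and tertiary granule list are raised in all 3 doxycycline libraries, and washed clone 1 has the highest level of the primary granule list, at 1.84.

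Differences between the clones that persisted through the 3 conditions were tested with the condition as a covariate. No gene passed by edgeR, where the smallest adjusted p was 0.0505, while 4501 genes lay at an unadjusted p under 0.05, DESeq2 called 2764 genes and limma voom 1013. The smallest p belonged to Ear1, an eosinophil ribonuclease of a family of close paralogs, which stood at or below 6.97 CPM in clone 1, 29.4 to 59.1 CPM in clone 2 and 23.1 to 47.1 CPM in clone 4. Rxra, the retinoid X receptor, stood at 7.46 to 33.9 CPM in clone 1 and 23.0 to 84.8 CPM in clone 2, and Cxcr4, a homing receptor, at 122 to 177 CPM in clone 1 and 41.9 to 57.2 CPM in clone 2. Dusp6, a phosphatase of the ERK pathway, stood at 103 to 125 CPM in clone 2 and 42.0 to 60.1 CPM in clone 4. The count turned on the library set: without clone 1 edgeR called 3067 genes between the other clones, and without the untreated libraries it called 1224.

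Whether the clones responded differently to the loss of the hairpin was tested as an interaction, with the untreated and washed libraries of a clone taken as 1 state. No gene passed by edgeR (407 at an unadjusted p under 0.05), limma voom called 0 and DESeq2 called 5. The smallest p belonged to Gapt, which went from 11.6 to 175 CPM in clone 1, 6.04 to 236 CPM in clone 2 and 3.83 to 222 CPM in clone 4 (adjusted p = 1). Kif1c, a kinesin, went from 34.9 to 3.79 CPM in clone 1, from 58.3 to 60.9 CPM in clone 2 and from 40.4 to 20.3 CPM in clone 4. Untreated and washed clone 1 were the least alike of the pairs taken as 1 state, as the correlations across genes above show.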

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

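The fits without the washed or the untreated library of clone 1, with the block but without the washed library of clone 1, and without mitochondrial and unnamed entries were chosen after the data were seen, and the others before. Of 153 called results of named genes, 1 passed under every alternative run, Ptpru in washed against doxycycline; of 204 uncalled ones, 68 passed under at least 1. Of 42 called list results, 4 passed under every alternative, those of the mature neutrophil and NADPH oxidase lists in doxycycline against untreated and in washed against doxycycline. No named gene passed in opposite directions. With clone 4 left out of the unblocked fit, 78 and 73 calls of named genes were lost in those comparisons. Each clone left out removes 3 libraries, yet 10 and 14 calls were lost without clone 1, and 44 and 55 without clone 2. The number of libraries alone therefore does not account for the differences between these fits. Clones 1 and 2, which remain without clone 4, were the least alike in the doxycycline and washed libraries. Their correlation across genes was 0.918 and 0.863, against 0.967 and 0.914 for clones 1 and 4. For clones 2 and 4 it was 0.959 and 0.961. Untreated libraries of different clones correlated at 0.966 to 0.970. Whether this accounts for the lost calls was not tested. The self-test recovered 38% of 2-fold changes with all libraries. Its spread was that of the blocked fit, and only 200 genes were made to differ between clones. Its recovery therefore does not give the power of the unblocked fit on these libraries, and modest changes can be missed.

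With the clone as a block, the counts were 2976 for doxycycline against untreated, 2744 for washed against doxycycline and 2271 reversed. Among named genes the block added 27 and 23 calls, and among lists 6, 1 and 2 over the 3 comparisons; it ended 0 calls and changed no other call of the genes and lists in the text. With the block and without the washed library of clone 1 they were 4732, 3820 and 3571. They were 412, 339 and 299 for glmTreat, which asks for more than a fold of 1.5, 2138, 1967 and 1649 for DESeq2, and 2026, 324 and 320 with only the compared groups fitted. With library size alone, washed against doxycycline gave 648 and reversal 594. Leaving out libraries in unblocked fits gave 0 to 2258, 4 to 1814 and 0 to 1660. The lowest came without clone 4 and the highest without the washed library of clone 1. Washed against untreated gave 0 under all alternatives run. The log2 fold change of Spi1 ran from 2.03 to 2.45 in doxycycline against untreated, 2.03 to 2.37 when libraries were left out, and from -2.49 to -2.05 in washed against doxycycline. Its calls in both were lost in the unblocked fits without clone 2 and without clone 4. Beyond the smaller sets of libraries and the stricter threshold, the cause was not tested.

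Called list results numbered 4 with an estimated correlation, 4 with that and the block, 16 by fry, and 25 to 46 when libraries were left out. Clone differences gave 74 genes with RLE factors, 1664 without the filter, 2764 by DESeq2, 1013 by limma voom and 0 to 3067 when libraries were left out. The interaction gave 5 by DESeq2. The cause was not tested.

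In washed against untreated, 12 lists turned direction by camera when libraries of clone 1 were left out, while a call stood on at least 1 side. Over the unblocked fits that left out libraries of any clone, the median log2 fold change ran from -0.23 to 0.82 for primary granule genes. It ran from -0.20 to 0.34 for secondary granule, -0.14 to 0.48 for cell cycle and -0.45 to 0.0746 for cell cycle inhibitor genes. For ribosome biogenesis it ran from -0.0312 to 0.41, for ribosomal protein from -0.33 to 0.0838 and for mitochondrially encoded genes from -0.64 to 0.20. For glycolysis it ran from -0.82 to 0.0825, for interferon from -0.42 to 0.0509 and for lysosomal genes from -0.20 to 0.0216. For mast cell genes it ran from -0.46 to 0.34 and for eosinophil genes from -0.24 to 0.31. Not all of these extremes came from leaving out libraries of clone 1. In the unblocked fits that did so, the lowest glycolysis median was -0.24 and the highest cell cycle median 0.38. With the block and without the washed library of clone 1, the medians were 0.0688 for secondary granule, -0.0147 for cell cycle, 0.0577 for ribosomal protein, -0.0191 for interferon and 0.0526 for lysosomal genes. The change follows from the libraries left out; why those libraries differ is weighed among the other observations.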

Other observations

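Except for the test of a few entries taking many counts in washed clone 1, the tests and library splits given here were chosen after the result was seen, and the hypoxia list was also chosen then.

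Genes of the hypoxia response, 25 tested of 26 given and 5 of them also in the glycolysis list, differed between libraries of one condition. Their mean level, as log2 CPM minus each gene's mean over all libraries, was 1.10, 1.28 and -0.07 in untreated clones 1, 2 and 4. It was -1.31, 0.39 and -0.96 in doxycycline and -1.71, 1.37 and -0.10 after washout. Within clones 1, 2 and 4 the mean changed by -2.41, -0.89 and -0.89 from untreated to doxycycline, and by -0.40, 0.98 and 0.87 from doxycycline to washed. In doxycycline against untreated 0 of them rose and 1 fell by edgeR's test, or 0 and 11 with the clone as a block, and the list gave p = 0.408 with an estimated correlation, 0.375 with the block.

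In washed clone 1, 435 of 9160 genes lay more than 2-fold beyond both the untreated and the doxycycline library of that clone, 104 above and 331 below, against 4 in clone 2 and 5 in clone 4. Hairpin-off cells left in the washed culture would place genes between those libraries, and the 435 genes argue against them as the whole cause. A part for them stays open, since washed clone 1 correlated at 0.923 with doxycycline clone 1 and at 0.922 with untreated clone 1. Genes called by the unblocked fit of the other clones leaned to doxycycline, with washed minus untreated medians of 0.18 for risen and -0.55 for fallen genes. Neutrophil lists raised by doxycycline did not. Their means in washed, untreated and doxycycline clone 1 were -0.90, -0.70 and 1.66 for mature neutrophil genes. For secondary and tertiary granule genes they were -0.89, -0.11 and 1.94. A library of another clone under this label is argued against by the genes that mark clone 1, of which 15 of 17 (88.2%) kept the side of clone 1. A few entries taking many counts are argued against by the 455 genes beyond both when mitochondrial and unnamed entries were left out, against 8 and 4 in clones 2 and 4. A change in the cells of this clone after washout stays open as a hypothesis, as do culture conditions and handling, which were not tested.

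The glycolysis list differed between libraries of one condition, with means of 0.65, 0.83 and -0.30 in untreated, -0.81, 0.53 and -0.51 in doxycycline and -0.99, 0.90 and -0.29 in washed clones 1, 2 and 4. Within those clones it changed by -1.46, -0.30 and -0.21 from untreated to doxycycline and by -0.18, 0.36 and 0.22 from doxycycline to washed. A few entries taking many counts are argued against for the differences between libraries, since 97.5% of the range was kept without mitochondrial and unnamed entries. No biological explanation was tested. Oxygen, medium and density at harvest were not measured and stay open, and so does the part of the hairpin state in the change from untreated to doxycycline.

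Doxycycline itself rather than the hairpin cannot be told apart as the source of the changes called in doxycycline against untreated, because no cells without the hairpin were given the drug in the libraries analysed here. Doxycycline can block mitochondrial translation, and a stress response to that would raise the ATF4 list. Its median log2 fold change was -0.57, but its members went both ways, with Atf3 and Slc7a11 called higher and Trib3 lower (2 higher and 8 lower with the clone as a block), so the median decides nothing and effects of the drug stay open.

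For doxycycline against untreated the real split gave 1311 genes, as many as 1 of the 10 splits of the 6 libraries, and the highest other gave 0. For washed against doxycycline the real split gave 1160, as many as 1 of 10, and the highest other gave 303, which set doxycycline clones 1 and 4 with washed clone 1; the highest other split that parted all pairs gave 0, and the blocked count was 2744. For washed against untreated 10 of 10 splits gave 0. In these comparisons 10 splits are too few for a share under 0.05.

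Of 60 sampled arrangements of the 9 libraries, 3 gave at least the 987 reversed genes, with 1198 as the highest other, so chance is not excluded at a share of 0.05. Those 3 kept the 3 doxycycline libraries together and gave 987 to 1198, and the others gave 0, which points to the doxycycline libraries as a structure of the samples. For the 42 called list results 26 of the 58 distinct partitions among them gave as many, with 55 as the highest other, and chance is not excluded. For the 4 list results called with an estimated correlation 2 of 58 gave as many, with 4 as the highest other. These arrangements ignored the clones. Among those with 1 library of each clone in each group, 4 of 108 gave at least 987 reversed genes, with 1012 as the highest other, a share under 0.05. The 4 kept the doxycycline libraries together and differed in exchanges of untreated and washed libraries. They set the doxycycline libraries apart from the others and no more. As the verdict differs between the 60 and the 108 arrangements, chance is left undecided for the reversed genes. For the lists 16 of 36 such partitions gave at least 42, with 52 as the highest other, and with an estimated correlation 3 of 36 gave at least 4, with 8 as the highest other, so chance is not excluded for either. The 4 partitions that kept the doxycycline libraries together gave 3 to 8 lists with an estimated correlation, and the others gave 0. For clone differences 36 of 36 arrangements of the clone labels gave at least the 0 genes called, with 0 as the highest other. For the 4501 genes at an unadjusted p under 0.05, 1 of 36 did, with 2980 as the highest other. That is the smallest share that 36 arrangements can give. As several such shares were examined without adjustment, it does not exclude chance. For the interaction 36 of 36 gave at least 0, with 0 as the highest other; for its 407 genes at an unadjusted p under 0.05, 18 of 36 did, with 3331 as the highest other, several times the real count, which points to a structure of the samples, and chance is not excluded.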
